A study of Arabidopsis thaliana with 2 samples.

How the data were processed

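Messenger RNA levels were measured by RNA sequencing in whole Arabidopsis thaliana seedlings of the Col-0 background, in 1 wild-type (WT) library and 1 jmj17-1 mutant library. The libraries were made with a TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, per the labels. The values used here are RPKM, reads per kilobase of feature and per 1000000 reads of the library, calculated by the authors and deposited as 1 table of 26743 features. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counter, the feature lengths and the use of strand are not given in the sources used here. The same table carries a Z score for each feature, deposited by the authors. For all 26743 rows this score equalled, within 1e-09, the Z of 2 proportions with the RPKM values entered as counts out of 1000000 in each library. The deposited p-value is the two-sided normal p of that score with no adjustment for the number of features, as tested on the same 26743 rows. RPKM values are not read counts, so this p takes no account of feature length, of the reads behind a value or of the spread between seedlings. The authors also deposited a list named for a p-value of 0.01 and a list named for a p-value of 0.05. Each of the 2 library columns was assigned by its title, and 0 columns of samples were left unassigned.

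Sequencing depth was estimated from the low RPKM values with the help of reference feature lengths. Of 1184 loci between 0 and 0.1 RPKM in both libraries, 1052 (88.9%) had a ratio between the libraries equal to a ratio of whole numbers up to 20 times a single depth ratio, within a relative 1e-05. This gave 53890006 reads behind the WT values and 45403267 behind the jmj17-1 values, a ratio of 1.19. Some loci stood at fractions of a read. With feature lengths from the RefSeq annotation of TAIR10.1, 6.57% of WT features above 0 came out at whole reads within 0.01, so the authors' lengths differed from these and every read number given here is approximate. A level of 1 RPKM on a feature of 1500 bases stood for about 80.8 reads in WT and 68.1 in jmj17-1. Of 25457 loci with an annotation identifier, 25133 were found in TAIR10.1 and 324 were not. A further 1286 features carried no annotation identifier, and how they were built is not given in the sources used here.

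The measure of change was log2 of (RPKM in jmj17-1 + 1) over (RPKM in WT + 1), which understates the change of low genes. Folds given beside RPKM values are plain ratios of RPKM without the added 1. The 18969 features with a mean RPKM of at least 1 over both libraries were analysed. With 1 library per genotype the difference has no replicate check, so no p-value was calculated and a fixed size rule was used, an absolute log2 ratio of at least 1 (2-fold). For named genes an exact Clopper-Pearson 95% interval of the share of approximate reads was converted to an interval of the fold. Such intervals cover counting error only. The median log2 ratio of each gene list was placed among the medians of 10000 random lists, in which each member was replaced by 1 of the 200 genes nearest in mean level. This percentile describes these 2 libraries and not the genotypes.

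The grouping, the size rule, 21 gene lists, the alternatives in the next part and the rule for naming genes were set before the data were examined. The rule named JMJ17, the 12 highest and the 12 lowest log2 ratios that passed the size rule among features with a mean RPKM of at least 5, and up to 4 members of each list that passed it. Where no member passed, the 2 with the largest absolute log2 ratio were given as values. The 3 most abundant genes of each library were also named. Because several of the extreme features were listed at 0 in 1 library, further genes with at least 1 RPKM in both libraries that passed the size rule were added. These were picked after their values were seen, mostly for having a known function, and genes between them in rank were passed over. 5 further lists, for rapid touch, wound and cold responses, low-sulfur responses, detoxification, and dawn-phased and evening-phased genes, were written after the main results were seen and left out the genes that had drawn attention to each response.

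The scripts were tested on simulated data. Reads were drawn for 25131 genes at the levels and depths of the jmj17-1 against WT comparison. With no gene changed, counting error alone put 1 gene past the rule upward and 0 downward. Of 200 genes changed 2-fold, 17% passed the rule, because the added 1 and counting error bring an exact 2-fold change to either side of the limit. Of 200 genes changed 3-fold and of 200 changed 4-fold, 100% passed. All changed genes had a mean of at least 5 RPKM, so these shares do not cover lower genes, where the added 1 weighs more. Among random lists of 20 genes, 3% fell outside the central 95%, and 100% of lists lowered by 0.3 were found below it. Near-identical and overlapping genes were sought in the TAIR10.1 transcripts with BLAST+ 2.17.0, on the same strand, at 95% identity or more over at least 50% of the transcript. Exon overlaps with genes of the opposite strand were listed separately, since without stated use of strand the reads of such pairs cannot be told apart. They concern, among the genes named here, EARLI1, AT4G22470, CYP81D11, DTX1, THA1, GUN4, LHCB2.3, LHCB4.2, LHCB1.3, LHCA4, PSBR, JMJ13, RAB18, F3H, PAP17, RVE1, FLC, TCH3, MYB73, CBF3, GSTF2, OPR2, APR3, AT2G23672 and AT1G45165, whose values are uncertain to that extent. The same holds for AT3G51238 and AT4G25670. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives for the pseudocount, the scaling, the low-level filter and the size rule were recalculated. Dark-grown seedlings, which the extraction protocol also mentions, were not analysed here.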

Results

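Transcripts were compared between WT seedlings and jmj17-1 seedlings, which carry a mutation in JMJ17, a demethylase of lysine 4 on histone H3. Whole seedlings were 7 days old and had grown on half-strength medium without sucrose under 16 h of light and 8 h of darkness. There was 1 library per genotype, so the difference has no replicate check, and every value below describes these 2 libraries. The values rested on an estimated 53890006 reads in WT and 45403267 in jmj17-1, and these estimates depend on reference feature lengths. In WT 18933 features reached 1 RPKM and in jmj17-1 18993 did. The most abundant transcripts of WT were LHCB1.3 at 7302 RPKM, RBCS1A at 7138 and LHCA4 at 4365, which encode light-harvesting proteins and the small subunit of Rubisco. In jmj17-1 they were RBCS1A at 6948 RPKM, LHCB1.3 at 6216 and PSBR, a photosystem II subunit, at 3596.

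JMJ17 (AT1G63490) was measured first, since it checks the labels. Its gene lies on the minus strand of chromosome 1, from 23544554 to 23553232 in TAIR10.1, with 5123 exonic bases. JMJ17 stood at 5.48 RPKM in WT and 2.90 in jmj17-1, 52.9% of the WT level (fold 0.529, 95% counting interval 0.483 to 0.580, from about 1514 and 675 reads). The log2 ratio of -0.73 did not reach the 2-fold rule. The position of the insertion is not given in the sources used here, and reads from outside an interrupted part of the gene can remain in a mutant.

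The genome-wide comparison asked which genes differ when JMJ17 is mutated. In jmj17-1, the touch-induced cell wall gene TCH4 and the phosphate-responsive family gene PHI-1 were among the most strongly lower transcripts, and the lipid-transfer-like EARLI1 was among the most strongly higher. Of 18969 features analysed, 74 were at least 2-fold higher and 110 at least 2-fold lower, 0.97% in all. The median log2 ratio of all features was 0.04 with an SD of 0.28 across features, and 96.6% lay within 1.5-fold. Across genes, which are not independent replicates, Pearson's r of the log2 levels was 0.987. The counts depended on the pseudocount, with 142 higher at 0.1 RPKM and 25 higher and 49 lower at 5 RPKM.

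Among the higher genes, EARLI1, which encodes a lipid-transfer-like protein, went from 147 RPKM in WT to 527 in jmj17-1 (3.58-fold, 3.48 to 3.67). Its relative AZI1, known from the priming of systemic defence, went from 94.6 to 271 RPKM, and a further lipid-transfer family gene, AT4G22470, from 8.01 to 29.7. GSTF6, a glutathione transferase, rose from 21.8 to 70.7 RPKM (3.25-fold, 3.06 to 3.46). CYP81D11, a cytochrome P450 induced by foreign chemicals, rose from 9.65 to 31.1 RPKM, the efflux carrier DTX1 from 3.002 to 10.5 and the threonine aldolase THA1 from 2.70 to 10.2. AT4G01870, a tolB-like protein, rose from 19.4 to 69.5 RPKM and AT1G27020 from 44.1 to 140 RPKM. The uncharacterized genes AT4G08555, AT1G65500 and AT5G26270 rose 4.05-fold, 3.71-fold and 3.71-fold from WT levels of 6.50, 4.66 and 4.54 RPKM. The glycine-rich protein gene GRP3S was the most abundant of these, at 456 RPKM in WT and 1273 in jmj17-1. EARLI1, AT4G22470, THA1, CYP81D11 and DTX1 overlap genes of the opposite strand, and their values are uncertain because the use of strand in counting is not given. AZI1, GSTF6, AT1G27020, THA1, CYP81D11, DTX1 and GRP3S were picked after their values were seen, and other genes between them in rank are not named.

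Among the lower genes, TCH4, a cell wall xyloglucan endotransglucosylase/hydrolase induced by touch, fell from 155 RPKM in WT to 27.5 in jmj17-1 (fold 0.178, 0.169 to 0.186). PHI-1, a phosphate-responsive family gene, fell from 32.6 to 3.97 RPKM (fold 0.122, 0.106 to 0.140). AT4G27280, a calcium-binding EF-hand protein, fell from 68.0 to 16.2 RPKM, and AT1G07135, a glycine-rich protein, from 159 to 40.6. Picked after their values were seen, with others between them in rank not named, were the defensin PDF1.2c at 15.2 and 3.299 RPKM and the calmodulin-like CML38 at 23.1 and 5.52. The transcription factor genes DREB26 and MYB77 went from 35.2 to 9.67 and from 46.5 to 13.1 RPKM. The low-sulfur response genes LSU3 and LSU1 went from 21.5 to 5.84 and from 12.1 to 3.01 RPKM.

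**Figure D1:**
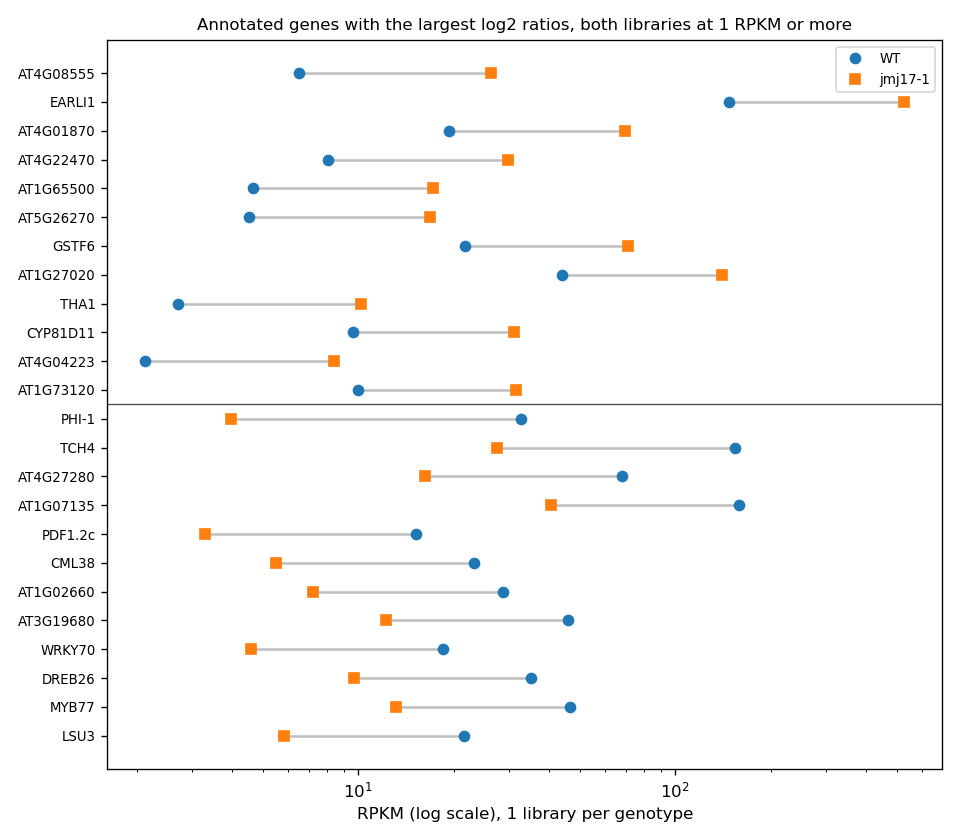
RPKM on a log axis in the WT library (circles) and the jmj17-1 library (squares) for the 12 annotated genes with the highest and the 12 with the lowest log2 ratio among those with a mean of at least 5 RPKM and at least 1 RPKM in both libraries. TCH4 stood at 155 RPKM in WT and 27.5 in jmj17-1, and EARLI1 at 147 and 527; there was 1 library per genotype and no error bar is drawn.

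Some of the most extreme features were close to 0 in 1 library and abundant in the other. AT1G59359 and AT1G58983, both ribosomal protein S5 family genes, stood at 0.008 RPKM in WT and at 109 and 106 RPKM in jmj17-1, while their near-identical copy AT1G58684 went from 271 to 106. The 3 loci are near-identical in sequence, so the division of reads between them is uncertain. AT3G01472 and AT4G19112 were listed at 0 in WT and stood at 22.4 and 21.6 RPKM in jmj17-1. AT1G48598 at 25.8 RPKM in WT, AT1G18020 at 21.04, AT2G23672 at 13.7, AT5G01712 at 12.8, AT3G02468 at 12.5, AT1G45165 at 11.9 and AT4G25672 at 11.0 were listed at 0 in jmj17-1. Of the 11 loci near 0 in 1 library, 6 are not in TAIR10.1 and could not be searched for genes that share their reads. Features outside the annotation also differed, with NOVEL_308 at 18.3 and 204 RPKM, NOVEL_631 at 1.95 and 9.27, and NOVEL_643 at 76.2 and 1.18. Without the loci at or under 0.1 RPKM in 1 library, an alternative chosen after seeing the data, 67 features were higher and 97 lower.

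Chlorophyll synthesis is the process named in the title of the series, in the transition from dark to light, and here it was measured in light-grown seedlings. None of the 31 chlorophyll and tetrapyrrole genes passed the 2-fold rule. The list had a median log2 ratio of 0.01, at percentile 8.61 of random lists, with 18 members above 0 and 13 below, and the sign of this median flipped to -0.03 when the median of all genes was set to 0. HEMA1, whose glutamyl-tRNA reductase opens the pathway, stood at 137 RPKM in WT and 97.4 in jmj17-1 (fold 0.713, 0.695 to 0.730). GUN4, a regulator of magnesium chelatase, stood at 91.4 and 71.1 RPKM (fold 0.778, 0.748 to 0.809), and overlaps a gene of the opposite strand, which leaves its value uncertain. The summed level of the list was 5902 RPKM in WT and 5489 in jmj17-1.

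The genes for light-harvesting proteins were lower as a set. Of 20 members 19 had a log2 ratio below 0, none passed the 2-fold rule, and the median was -0.37 (fold 0.775), a value that 0 of 10000 matched random lists reached. LHCB2.3 stood at 524 RPKM in WT and 346 in jmj17-1 (fold 0.661, 0.650 to 0.672), and LHCB4.2 at 1394 and 944 RPKM (fold 0.678, 0.671 to 0.684). Nuclear genes for the photosystems, electron transport and Rubisco went the same way, with 29 of 30 below 0 and a median of -0.24 (fold 0.846), again reached by 0 of 10000 random lists. For both lists the match on level was loose. Of the light-harvesting genes 16 lie at a mean of at least 1000 RPKM, where there are 54 features in all. Most of their 200 nearest genes were therefore less abundant. PSAD2, a photosystem I subunit gene that overlaps a neighbour, stood at 666 and 472 RPKM and RBCS3B, a small subunit of Rubisco, at 4094 and 3050. The 3 photosynthesis lists, chlorophyll synthesis included, held 16.9% of the summed RPKM in WT and 14.1% in jmj17-1. Under quantile normalization the medians shrank to -0.10 (bootstrap 95% interval -0.21 to -0.068) and -0.08 (-0.11 to -0.023), with 16 of 20 and 21 of 30 members below 0. Among random lists drawn on the same scale, a comparison chosen after seeing the data, 109 of 10000 then reached the light-harvesting median and 50 the other. Under the other scalings tried, 0 of 10000 reached either median. Those scalings shift the abundant genes nearly alike, so a list and its random lists move together and these counts could hardly change. Of 54 features at a mean of at least 1000 RPKM 38 are in the 3 photosynthesis lists, so quantile normalization takes much of their change away by construction. It moved the median of the 14 other nuclear genes at that level from 0.0043 to 0.21. LHCB1.3 is near-identical to LHCB1.1 and LHCB1.2, and RBCS3B to RBCS2B, so the division of reads between them is uncertain, and LHCB2.3 and LHCB4.2 overlap genes of the opposite strand.

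Light signalling genes did not move in 1 direction, and none of 26 passed the 2-fold rule. Their median log2 ratio was 0.07, at percentile 73.6. PIF4, a phytochrome-interacting factor that promotes elongation, stood at 55.1 RPKM in WT and 32.8 in jmj17-1 (fold 0.596, 0.574 to 0.620). ELIP1, an early light-induced protein gene, stood at 5.01 and 8.81 RPKM (fold 1.76, 1.51 to 2.06). Histone H3 demethylases and H3K4 methyltransferases other than JMJ17 had a median of 0.04 over 20 members, at percentile 63 (0.076 over the 13 with a mean of at least 5 RPKM), and none passed. JMJ13 stood at 4.44 and 3.51 RPKM and REF6 at 6.65 and 7.51.

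A few defence and wound genes were lower, and other members of both lists were not. Of 11 salicylic acid and pathogen defence genes 2 were at least 2-fold lower and none higher. Of these genes 7 lay below 0 and 4 above, and the median of -0.17 stood at percentile 0.13 of random lists, with a bootstrap 95% interval over members of -0.998 to 0.092. At a mean of at least 10 RPKM the median was -0.998 over 3 members. WRKY70, a transcription factor of salicylic acid signalling, fell from 18.5 to 4.59 RPKM (fold 0.248, 0.218 to 0.280), and PR2, a glucanase, from 2.84 to 0.88 RPKM. Of 12 jasmonate and wound genes 2 were at least 2-fold lower and none higher. Here 8 lay below 0 and 4 above, and the median of -0.17 stood at percentile 0.03, with a bootstrap interval of -0.54 to 0.075, and was -0.088 at a mean of at least 5 RPKM. JAZ7, a repressor of jasmonate signalling, fell from 2.11 to 0.24 RPKM and VSP2, a vegetative storage protein gene, from 8.55 to 3.26. With a pseudocount of 5 RPKM PR2, JAZ7 and VSP2 no longer passed, at log2 ratios of -0.41, -0.44 and -0.71, while WRKY70 did. In the abscisic acid and water deficit list none of 22 passed, and the median was -0.04 at percentile 2.24, with a bootstrap interval of -0.16 to 0.098. Over the scalings tried this median ranged from -0.10 with the trend on level removed to -0.029 when rescaled without organelle genes. Members of this list went both ways, with 13 below 0 and 9 above. COR15A stood at 21.4 and 11.0 RPKM and RAB18, a dehydrin gene, at 7.96 and 3.96, while KIN1, named after its value was seen as the highest of the list, stood at 19.3 and 34.6.

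Of 13 iron status genes 1 was at least 2-fold higher, IMA1, an iron-deficiency peptide gene, at 5.94 and 13.0 RPKM (fold 2.19, 1.88 to 2.57). It lay close to the rule, with a log2 ratio of 1.01 that was 0.97 with the median of all genes set to 0 and 0.72 with a pseudocount of 5 RPKM. The iron list median was 0.12 at percentile 90.5, and 0.30 over the 7 members with a mean of at least 5 RPKM. None of 13 flavonoid genes passed, with a median of 0.11 at percentile 88.2, F3H at 7.45 and 14.9 RPKM and LDOX at 3.47 and 2.21. F3H overlaps AT3G51238 on the opposite strand, which went from 6.91 RPKM in WT to 0 in jmj17-1, so the F3H difference is uncertain. None of 6 phosphate starvation genes passed, with a median of 0.05 at percentile 54.6 (0.33 over the 4 with a mean of at least 5 RPKM), PAP17 at 7.70 and 14.2 RPKM and PHT1;4 at 9.22 and 13.4. None of 12 clock genes passed, with a median of 0.07 at percentile 65.8, RVE1 at 2.92 and 1.52 RPKM and PRR5 at 41.5 and 55.1. None of 6 flowering time genes passed, with a median of 0.18 at percentile 97.1 (0.017 over the 3 with a mean of at least 5 RPKM), the floral repressor FLC at 2.06 and 3.02 RPKM and MAF5 at 0.92 and 1.42. None of 8 auxin and shade genes passed, with a median of -0.03 at percentile 20.7 (-0.32 over the 2 with a mean of at least 5 RPKM), IAA1 at 9.08 and 5.67 RPKM and IAA19 at 5.45 and 3.54. None of 4 heat shock genes passed, with a median of 0.06 at percentile 59.9, HSP18.2 at 3.93 and 5.05 RPKM and HSP90.1 at 3.86 and 3.35.

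Markers of other organs and of RNA composition were measured alongside. None of 14 root markers passed, with a median of 0.03 at percentile 49.2 that turned to -0.0135 when the median of all genes was set to 0, WOX5 at 0.94 and 2.06 RPKM and PRP3 at 14.4 and 19.9. Of the seed storage and late embryogenesis markers only 2 were analysed, and both were lower in jmj17-1. The cruciferin genes CRU3 and CRA1 fell from 6.34 to 0.55 and from 7.39 to 1.70 RPKM, and CRA1 no longer passed with a pseudocount of 5 RPKM. The 9 commonly used reference genes had a median of 0.10 at percentile 80.1, with UBQ10 at 390 and 484 RPKM and GAPC1 at 427 and 511, and their median stayed above 0 under every scaling tried. Of 57 plastid-encoded features 1 passed, ATCG01210, at 202 RPKM in WT and 66.6 in jmj17-1. It was not in the search for near-identical copies, so a different division of reads between copies is not excluded. The list ranged from this feature at a log2 ratio of -1.59 to 0.95, with 33 above 0 and 24 below. Its median was 0.07 at percentile 84.6 (0.24 over the 11 with a mean of at least 10 RPKM). None of 6 mitochondria-encoded features passed, with a median of 0.0018 at percentile 34.9 that turned to -0.0402 under the same setting, ATMG00990 at 0.99 and 1.73 RPKM and ATMG00665 at 1.80 and 1.07.

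**Figure D2:**
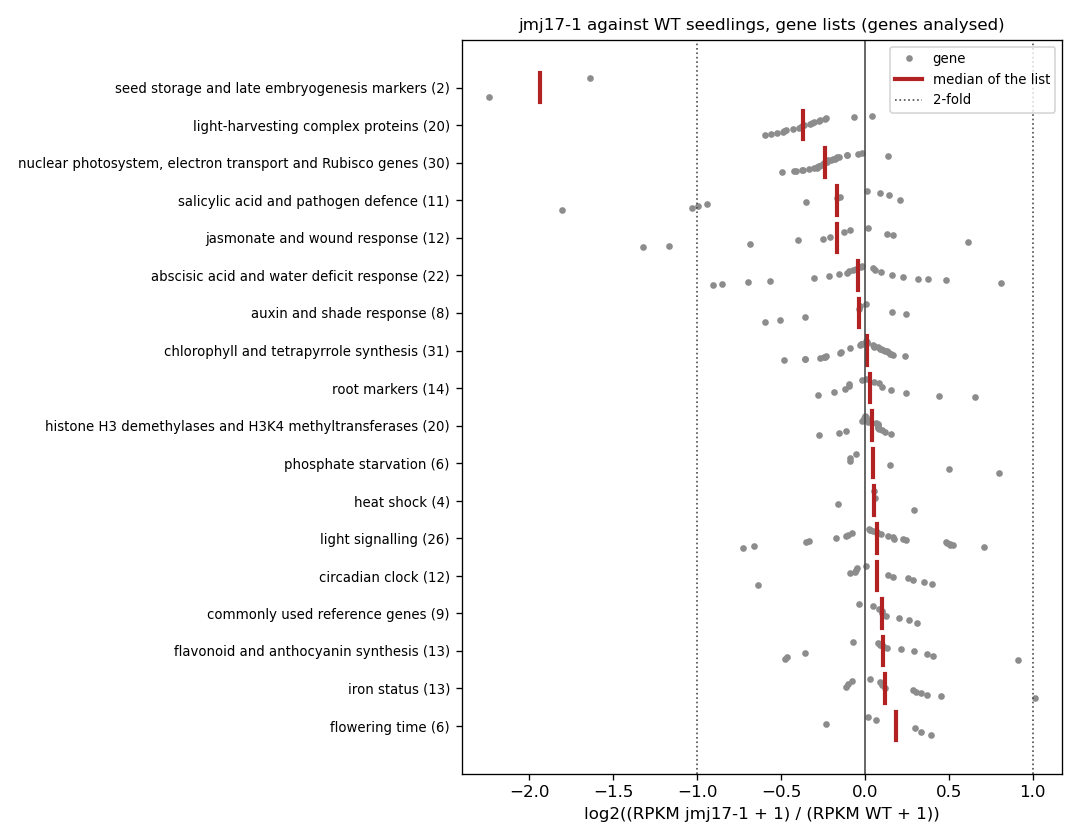
Log2 ratio of jmj17-1 over WT, with 1 RPKM added to each value, for the genes of each nuclear list (grey points, spread vertically for visibility) with the list median (red bar), dotted lines at 2-fold and the number of genes in parentheses. Of the light-harvesting genes 19 of 20 lie left of 0 around a median of -0.37. The 31 chlorophyll and tetrapyrrole genes lie on both sides of 0 around a median of 0.01. That median turned to -0.03 when the median of all genes was set to 0. The 14 of them in the chlorophyll branch had a median of -0.14, with 9 below 0 and 5 above.

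The authors' deposited table named for a p of 0.05 held 410 genes, 161 higher and 249 lower in jmj17-1. It ran somewhat past its named limit, with 396 of the 410 genes at or under a deposited p of 0.05. Of 81 genes of the 3 photosynthesis lists 47 were in the authors' deposited table at 0.05, 46 of them lower, as were 17 of the 20 light-harvesting genes. The deposited p depends on level, and these genes are abundant, so random lists matched on mean level were drawn, a comparison chosen after seeing the data. Of 10000 such random lists the median held 19 genes of the authors' deposited table, 95% held 12 to 26, and 0 held as many as 47. The match is loose at the top, since 38 of the 54 features at a mean of at least 1000 RPKM are photosynthesis genes. Many replacements were less abundant, so the effect of level on the deposited p was not removed. In the authors' deposited table at 0.05, 106 genes were at least 2-fold and 210 at least 1.5-fold different on the scale used here. Its median gene stood at 112 RPKM, against 10.2 for all features analysed. A further 78 features that passed the 2-fold rule were absent from the authors' deposited table at 0.05, and their median level was 3.27 RPKM. By the deposited formula a 2-fold ratio reaches a p of 0.05 only from 11.5 RPKM in the lower library, and the median levels of the 410 listed genes and of the 78 others stood on either side of that level. The authors' deposited table named for a p of 0.01 held 288 genes, 102 higher and 186 lower, with 45 photosynthesis genes, all 45 lower. Of the 288 genes, 261 were at or under a deposited p of 0.01. JMJ17 had a p of 0.372 in the authors' deposited table.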

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

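List medians kept their sign under the alternatives run, except 3 that lay near 0, those of the chlorophyll, root marker and mitochondria-encoded lists. Setting the median of all genes to 0 brought the root marker median to -0.0135 and the mitochondria-encoded median to -0.0402. No paired analysis was possible because there was 1 library per genotype, and for the same reason leaving out a library was not an option. A comparison of raw counts, set before, was not run, since RPKM values were analysed here, and the loess trend was run as a running median. The alternatives without loci near 0, without unannotated features, with random lists drawn without photosynthesis genes and with random lists drawn under each scaling were chosen after seeing the data. Of 214 recalculated list medians 184 moved by less than the bootstrap spread of the list and 30 by more. The largest shift of the median of all genes by a scaling was 0.042. The share of passing features that were higher was 40.2%, and over the pseudocounts, scalings and low-level filters it ranged from 33.5% with the median set to 0 to 47.2% with a pseudocount of 0.1 RPKM. It was 44.0% at 1.5-fold and 26.9% at 4-fold, where few features pass.

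The 74 higher features became 142 with a pseudocount of 0.1 RPKM, 25 with 5 RPKM, 38 at a mean of at least 10 RPKM, 287 at 1.5-fold and 7 at 4-fold. The 110 lower features became 49 with a pseudocount of 5 RPKM, 71 at a mean of at least 5 RPKM, 52 at a mean of at least 10, 366 at 1.5-fold and 19 at 4-fold. Stricter filters and size rules pass fewer features by construction. The log2 ratio of JMJ17 was -0.90 with a pseudocount of 0.1 RPKM and -0.41 with 5 RPKM. In the authors' deposited table at 0.05, 210 genes passed at 1.5-fold.

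With the median of all genes set to 0, with TMM-like scaling and with the trend on level removed, in that order, the chlorophyll list median was -0.031, -0.034 and -0.056, a change of sign from 0.01. The light-harvesting median was -0.41, -0.41 and -0.41, the photosystem and Rubisco median -0.28, -0.29 and -0.29, and the histone list median 0.00032, 0.0014 and 0.0092. Quantile normalization gave -0.10 for light-harvesting genes, -0.083 for photosystem and Rubisco genes and 0.051 for reference genes, whose median was 0.057 with TMM-like scaling and 0.0495 with the trend removed. At a mean of at least 5 RPKM the medians were 0.076 for the histone list, -0.32 for auxin, 0.017 for flowering time, 0.30 for iron and 0.33 for phosphate. At a mean of at least 10 RPKM they were -0.998 for salicylic acid, 0.017 for flowering time, 0.33 for phosphate and 0.24 for plastid-encoded features, with fewer members in each. The seed marker median was -2.68, -2.27 and -0.96 with pseudocounts of 0.1, 0.5 and 5 RPKM, and -0.30 with no filter on low values. Beyond the filters, the cause of these shifts was not tested. Depth limits low genes most, since at the estimated depths 3 reads on 1500 bases equal 0.037 RPKM in WT and 0.044 in jmj17-1.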

Other observations

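The 5 lists used in this part were written after the main results, whose table of passing features already held the members past the 2-fold rule, although no value of a member had been looked up. The tests on root markers, on other genes of green tissue and on handling were chosen after the result they bear on was seen. The bootstrap bound on the harvest-time test was also added after its value was seen. Genes of rapid responses to touch, wounding and cold were lower in jmj17-1 as a set. Of 19 genes analysed 18 were below 0 and 8 at least 2-fold lower, and the median log2 ratio of -0.68 was reached by 0 of 10000 matched random lists. TCH3, a calmodulin-like touch gene, fell from 163 to 70.2 RPKM, the ethylene response factor ERF6 from 27.5 to 10.6 and MYB73 from 96.0 to 39.6. CBF3, a regulator of cold responses, was the only member above 0, at 0.87 and 1.93 RPKM. CZF1 at 27.97 and 27.77 RPKM and WRKY18 at 10.15 and 10.13 hardly differed, although both count among the 18 below 0.

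Detoxification genes were higher. Of 12 analysed 11 were above 0 and 3 at least 2-fold higher, with a median of 0.67 that 0 of 10000 random lists reached. The glutathione transferase genes GSTF2 and GSTF7 rose from 44.7 to 100 and from 14.5 to 32.9 RPKM, and the glucosyltransferase UGT74E2 from 1.66 to 5.62. OPR1 and OPR2, near-identical copies, stood at 73.7 and 111 RPKM and at 17.9 and 27.9. Low-sulfur genes were lower, with 6 of 7 below 0 and a median of -0.69, which 0 of 10000 random lists reached. SDI1 fell from 3.66 to 1.11 RPKM, SHM7 stood at 45.9 and 24.2, and APR3, a sulfate-reducing enzyme gene, at 110 and 102. The hypotheses that the detoxification response as a whole is higher (median 0.67) and the low-sulfur response as a whole lower (median -0.69) in the jmj17-1 library were drawn from other genes of the same 2 libraries, so these medians show that the pattern extends to further genes and are not independent evidence. The members that pass the 2-fold rule are already among the 184 features counted in the main comparison. An effect of the mutation and a difference in how the seedlings grew were not separated, with 1 library per genotype.

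The lower light-harvesting transcripts were weighed against 3 explanations. A bias that compresses abundant genes in 1 library is argued against by 426 other abundant genes, whose median log2 ratio was 0.079 (bootstrap 95% 0.059 to 0.094), where the bias needed -0.18 or lower. At a mean of at least 1000 RPKM, a limit added after the result was seen, 11 such genes had a median of 0.045 (-0.052 to 0.18). Removing the trend on level left the light-harvesting median at -0.41. That running median spanned far more genes than the 54 features at a mean of at least 1000 RPKM, so it could not follow a bias limited to them. Quantile normalization took the light-harvesting median to -0.10. It decides nothing either, since 38 of those 54 features are in the photosynthesis lists. Giving both libraries 1 distribution removes much of their change by construction. A smaller share of green tissue in jmj17-1 seedlings, as the whole cause, would lower all genes of green tissue by the same factor. The photosystem and Rubisco median was -0.24, and the light-harvesting median minus this was -0.13 (bootstrap 95% -0.23 to -0.041). The 14 genes of the chlorophyll branch, which follows the split from heme synthesis, had a median of -0.14 (-0.24 to 0.055), and the light-harvesting median minus theirs was -0.22 (-0.44 to -0.075). This argues against green tissue as the whole cause only if these genes are expressed in green tissue alone, which was not tested. The intervals cover the spread of genes and not of libraries. As part of the cause a smaller green share stays open, since these sets had medians below 0. It would also raise root markers, and their median of 0.029 lay too close to the 0.042 of all genes to decide. A later time of harvest for jmj17-1 would raise evening-phased over dawn-phased genes. Their difference was -0.10, the direction opposite to this, and by the limit first set it would be excluded, but its bootstrap interval of -0.73 to 0.19 passed the 90th percentile of random pairs at 0.13, so harvest time stays open. An effect of the mutation is also open and untested.

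For the lower touch and wound transcripts, the hypothesis that the rapid response as a whole is lower in the jmj17-1 library extended to the separate list, with a median of -0.68. That list comes from the same 2 libraries and is not independent evidence, and its 8 genes past the rule are among the 110 lower features. Handling of the seedlings before the RNA was taken may change these genes within minutes, and with 1 library per genotype, different handling of the 2 genotypes cannot be told apart from the mutation. A later harvest was not decided either, with the same difference of -0.10 between evening-phased and dawn-phased genes.

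Of 11 loci at or under 0.1 RPKM in 1 library and at 10 RPKM or more in the other, 5 were searched in the reference annotation, and 6 are not in it. Reads shared with a near-identical or overlapping gene and assigned differently in each library are a candidate explanation. Of the 5 searched, 3 (60%) had such a partner, against 31 of 500 other genes (6.2%, Fisher's exact test, one-sided p = 0.00255 across genes of these libraries), although 2 of the 3 are copies of each other. How reads were assigned was not measured. For the 6 loci outside the annotation, shared reads were not tested and stay open. AT4G25672 went from 11.0 RPKM in WT to 0 in jmj17-1, while AT4G25670, near it in locus number, went from 10.2 to 21.8. AT1G48598 went from 25.8 to 0, while AT1G48600 went from 22.3 to 46.1. Each of these is among the 184 passing features. Neighbours of the other unsearched loci were not looked at. Summed over AT1G58380, AT1G58684, AT1G58983 and AT1G59359, the ribosomal protein S5 family stood at 432 RPKM in WT and 502 in jmj17-1. AT1G18020 went from 21.04 RPKM to 0 while its near-identical copy AT1G17990 went from 6.59 to 15.9. AT2G23672 and AT1G45165 had no partner on their own strand and overlap AT2G23670 and AT1G45163 on the opposite strand.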
